A study of Mus musculus with 2 samples.

How the data were processed

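DNase-seq libraries from the thymus of 2 male B6CASTF1/J mice at 10 days of age were analysed from the deposited files. The labels place both in 1 group and number them as biological replicates 1 and 2, and name a different male for each. No comparison between groups was possible, so no test compares animals.

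For each library the deposited files held 2 peak lists, a footprint list and a cut rate list, all on the mm10 build per the labels. The peak value is a signal that the authors computed for each library, per the file contents in whole multiples of a fixed step, and its scale is not given in the sources used here. All peak values lay within 0.05 of a step of a whole multiple. Peaks were called per library, since the authors deposited separate lists. The aligner, the peak caller and the footprint caller with their versions are not given in the sources used here. The cut rate lists hold, per the labels, a false discovery rate (FDR, a q-value) deposited for short intervals, all at most 0.05. The footprint list deposited for each library carries the same p-value-like threshold of 0.01 in every line, so footprints could not be ranked. When the peaks were set beside the cut rate lists, each peak of the larger list overlapped an interval with an FDR under 0.05. Each peak of the smaller list overlapped one with an FDR under 0.001. The larger list was used throughout and the smaller one as an alternative.

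Peaks of the replicates were compared by an overlap of at least 1 bp in each direction and by the Jaccard index of covered bases. Overlapping peaks were merged, and a merged region holding a peak of each replicate counts as a shared peak, centred on its midpoint. Genes and transcript starts came from GENCODE mouse release M21, whose assembly, GRCm38, is the assembly of mm10. Peaks within 1 kb of any annotated start were called promoter peaks. A promoter of a protein-coding gene was called open where a peak of each replicate overlapped the window of 1 kb either side of 1 of its starts. Each shared peak was assigned to the protein-coding gene with the nearest start, up to 100 kb away.

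The gene lists, the motifs, the tests and the alternatives were fixed before the data were examined. The 15 lists held 220 genes for T lineage, B lineage, myeloid, dendritic, thymic epithelial, fibroblast, endothelial, erythroid, adipose, hepatocyte, neuron, muscle, cell cycle, housekeeping and developmental genes. Ahsp of the erythroid list was not matched to the annotation. Open promoters of a list were compared with those of all other protein-coding genes by a two-sided Fisher's exact test with Benjamini-Hochberg adjustment over the lists. Genes were not matched on the number of annotated starts, and a start within a gene could make its promoter count as open. The median number of shared peaks per gene of a list was placed among those of 10000 random lists of the same size, matched on the length of the gene's territory in 20 bins, and values beyond percentiles 2.5 and 97.5 were called. The 25 motifs were fixed consensus sequences matched on both strands. Peak windows of 150 bp were compared with windows of the same size 500 bp to each side that overlapped no peak. Footprints widened by 5 bp were compared with intervals of the same length placed at random in the same peaks and free of footprints. Footprints whose peak had no room for such an interval were left out. Both used two-sided Fisher's exact tests with Benjamini-Hochberg adjustment over the motifs and a threshold of 0.05. Where the background held no match, the fold was taken against a floor of 3 counts, as a lower bound. Overlapping motifs of related factors were not told apart. Peak densities were taken per Mb of known bases.

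Named genes followed a fixed rule. Always named were Cd4, Cd8a, Rag1, Rag2, Ptcra, Cd3e, Tcf7, Bcl11b, Gata3, Lck, Foxn1 and Aire. Added were the 12 members of the T lineage list with the most shared peaks and up to 8 with a closed promoter, of which there were none. From each other list came the 3 members with the most shared peaks and up to 3 that went against the majority of their list. Also named were the 10 protein-coding genes with the most shared peaks and the 5 shared peaks with the highest mean rank of the peak value, with ties broken by symbol. Not every gene that the rule picks is named in the text.

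Alternatives were a reciprocal overlap of 50%, the stricter 50% of each replicate's peaks, the same number of top peaks from each replicate, the smaller peak list, promoter windows of 250 bp and 2500 bp, a limit of 20 kb or no peaks within 1 kb of a start for assignment, equal numbers of peak windows and flanks drawn from each GC bin of 5% (59354 of 80482 peak windows), windows of 50 bp, distal peaks alone, footprints without a margin, log2 values, and each replicate alone. Intervals are 95% Wilson intervals. They and the p-values cover counting error only, since peaks, windows and genes are not independent and PCR copies are not independent molecules. Means with SD are over the 2 replicates.

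The steps were tested on simulated data. Of 200 random gene lists, 4% fell outside the middle 95% of matched lists and 3.5% had a Fisher p under 0.05. Of 200 simulated lists given 3 times the peaks, 99.5% were found. Of 200 simulated lists of 16 genes with nearly all promoters open, 96.5% were found. All simulated lists held 16 genes, and simulated peak counts were drawn at random in proportion to territory length. The spread of the real counts, smaller lists and lists with few open promoters were not simulated, so these shares need not hold for them. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and numba 0.67.0, with figures from matplotlib 3.10.9.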

Results

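DNase-seq maps accessible chromatin by cutting nuclear DNA with DNase I and sequencing the cut ends. It was applied here to the thymus, the organ in which T cells mature, of male mice at 10 days of age. The animals were B6CASTF1/J, the first-generation cross of the laboratory strain C57BL/6J and the wild-derived strain CAST/EiJ. The samples form 1 group of 2 replicates, each labelled as a different male, with no treated or control group. The design therefore supports a description of thymus chromatin and a comparison of the replicates with each other. The peak set used throughout held 95913 peaks covering 18.6 Mb in replicate 1 and 161763 peaks covering 32.7 Mb in replicate 2, with a median width of 180 bp in each. Peak values rose in equal steps of 0.00445 in replicate 1 and 0.00510 in replicate 2. If a step is worth 1 tag after scaling by library size, replicate 1 was sequenced 1.15 times as deeply. The scale is not given in the sources used here, so the absolute depth is unknown.

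The comparison of the replicates asks how much of the accessible chromatin was found in both. Promoters of T lineage genes such as Cd4, Cd8a, Lck and Rag1 had a peak in each replicate, and replicate 2 had more peaks in all. Of the peaks of replicate 1, 83146 overlapped a peak of replicate 2, or 86.7% (95% Wilson interval 86.5 to 86.9). Of the peaks of replicate 2, 83132 overlapped a peak of replicate 1, or 51.4% (95% Wilson interval 51.1 to 51.6). The covered bases had a Jaccard index of 0.415. Merging overlapping peaks gave 80482 regions with a peak of each replicate, called shared peaks from here on. With the same number of top peaks taken from each replicate, 77.8% of those of replicate 2 were shared. Across shared peaks, which are not independent replicates, the peak value had a Pearson and a Spearman correlation of 0.95 each between the replicates. The value was higher in replicate 2 at 95.6% of shared peaks, with a median log2 ratio of 0.86 and an interquartile range from 0.57 to 1.14.

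**Figure D1:**
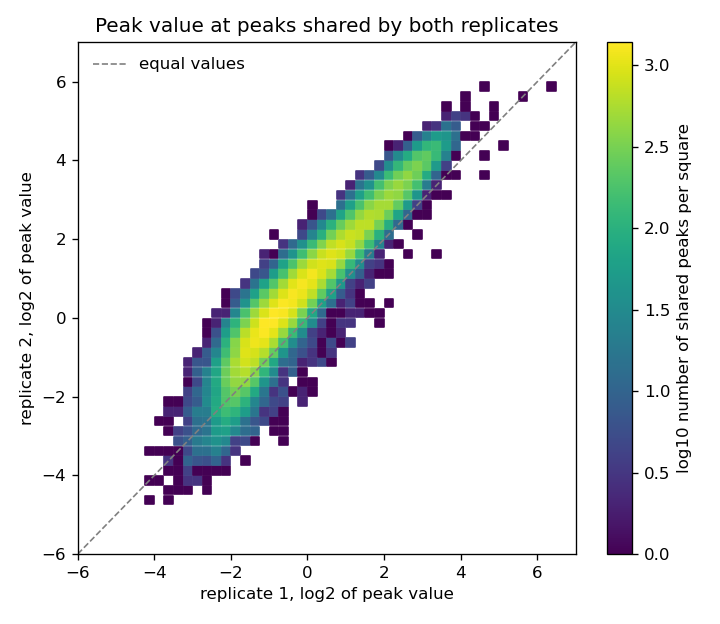
Peak value at the 80482 shared peaks, as log2 of the deposited value in replicate 1 (horizontal) and replicate 2 (vertical), with colour for log10 of the number of shared peaks in each square. The dashed line marks equal values, and most squares lie above it, with a median log2 ratio of 0.86.

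Shared peaks lay mostly at transcription starts, in introns and between genes. In all, 36.4% were centred within 1 kb of an annotated start (29281 of 80482, 95% Wilson interval 36.1 to 36.7). A further 32.2% lay in introns and 26.8% between genes, while coding exons held 1.72%, untranslated regions 1.48% and other exons 1.34%. Peaks near a start had higher values than the others, with medians of 1.21 and 0.663 in replicate 1 and of 2.19 and 1.31 in replicate 2. The share near a start was 32.8% ± 5.39 (SD, n = 2) when each replicate's own peaks were counted. With a narrower window, 22.3% of shared peaks lay within 250 bp of a start.

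Genes of the thymocyte and T lineage list had open promoters throughout and the highest median number of shared peaks of the 15 lists. All 35 of its members had a promoter open in both replicates, against 64.3% of the other protein-coding genes (two-sided Fisher's exact test, p = 2.97e-07, Benjamini-Hochberg adjusted p = 4.46e-06 over 15 lists). Its members had a median of 11 shared peaks nearest to them, against 3 for random lists matched on territory length, at percentile 100 of 10000 such lists. The list includes surface receptors and signalling proteins of T cells as well as the transcription factors that set the lineage. The most shared peaks were nearest to Ets1 with 33, Runx1 with 33, Lef1 with 32, Tcf7 with 31, Satb1 with 30 and Runx3 with 29. All of these encode transcription factors or, for Satb1, a chromatin organiser. Dntt, which encodes the terminal transferase that adds bases to rearranging receptor genes, had 24 shared peaks. Thy1 had 24, Cd247 23, Ikzf1 23, Bcl11b 20 and Cd2 20. The genes with the fewest were Rag1 and Rag2, the recombinase pair, with 1 each. The promoter peak of Rag1 is not in its count, because each peak went to 1 nearest start, and replicate 2 alone had 9 peaks nearest to Rag1 and 5 nearest to Rag2. Replicate 2 alone had 102 peaks nearest to Ets1 and replicate 1 alone 34. The counts of 65 of the 92 genes picked by the naming rule moved by over 1.5 times with replicate 2 alone. There, 161763 peaks took the place of 80482 shared peaks, so counts rose in general, and the share of all genes that moved was not counted.

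At the coreceptor genes, Cd8a (ENSMUSG00000053977, chromosome 6, 71373427 to 71379173, mm10) had 9 shared peaks and Cd4 (ENSMUSG00000023274, chromosome 6, 124864692 to 124888221) had 7. The highest promoter peak of Cd8a, at 71373341 to 71373560 in its untranslated region, had a value of 5.07 ± 1.59 (SD, n = 2). That of Cd4, at 124888121 to 124888340, had 1.95 ± 0.586 (SD, n = 2). The highest peak nearest to Cd4 lay 2.85 kb from a start, in an intron at 124885221 to 124885480, with 3.32 ± 1.55 (SD, n = 2). Lck, the kinase that binds both coreceptors (ENSMUSG00000000409, chromosome 4, 129548344 to 129573641), had 8 shared peaks. The highest was also its promoter peak, at 129556521 to 129556720 with 7.19 ± 2.70 (SD, n = 2). It lay 162 bp from an annotated start and within an intron of the gene. Cd3e, a chain of the T cell receptor complex (ENSMUSG00000032093, chromosome 9, 44998740 to 45009627), had 10 shared peaks, the highest at 45022901 to 45023080, between genes and 13.4 kb from a start. Ptcra, the gene of the pre-T cell receptor alpha chain (ENSMUSG00000036858, chromosome 17, 46755663 to 46763712), had 3, and its promoter peak had 2.23 ± 0.428 (SD, n = 2). Gata3 (ENSMUSG00000015619, chromosome 2, 9857078 to 9890034) had 14 shared peaks and Bcl11b (ENSMUSG00000048251, chromosome 12, 107910403 to 108003602) had 20. The promoter peak of Bcl11b, 479 bp from a start, had 5.67 ± 2.41 (SD, n = 2). The promoter peaks of Rag1, at 101649421 to 101649720 on chromosome 2, and of Rag2, at 101624581 to 101624800, had 4.63 ± 2.47 and 4.04 ± 1.82 (SD, n = 2). Tcf7 (ENSMUSG00000000782, chromosome 11, 52252371 to 52283014) had its highest shared peak, by the mean of the replicates as for the other genes, 14.5 kb from its start, between genes at 52297461 to 52297640, with 5.50 ± 0.648 (SD, n = 2). In replicate 2 this peak had 5.95, below a peak within the gene at 52275441 to 52275700 with 6.44.

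**Figure D2:**
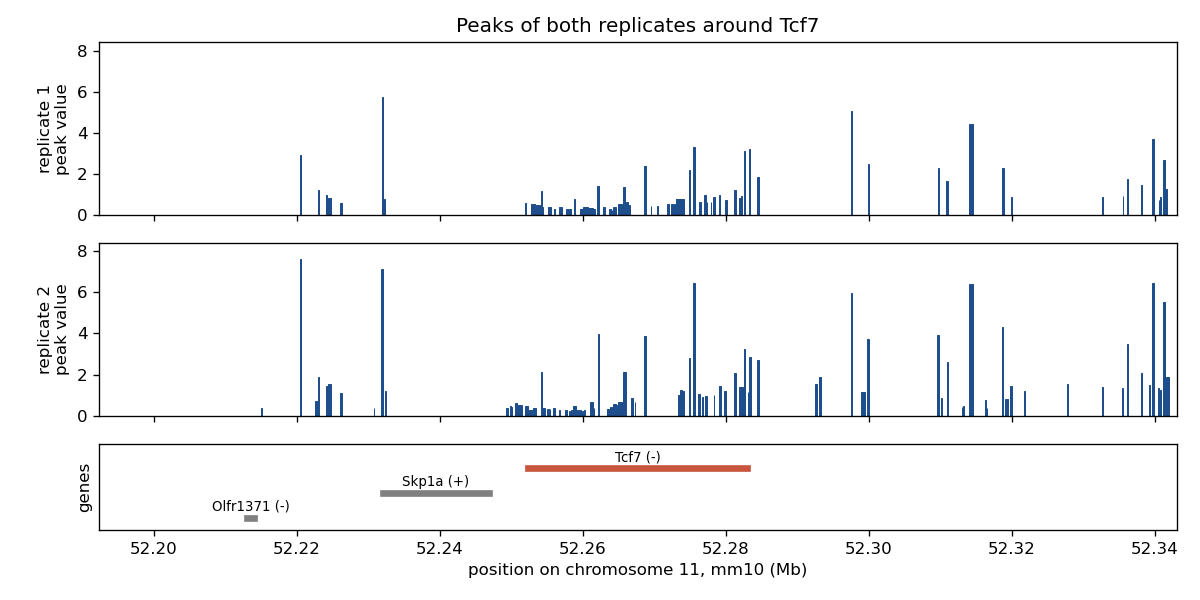
Peaks of each replicate around Tcf7 on chromosome 11 (mm10), from 60 kb before the gene to 60 kb after it, with protein-coding genes and their strand drawn below. Bars have the width of each peak and the deposited peak value as height, on 1 vertical scale, and the peak 14.5 kb from the start of Tcf7 appears in both replicates.

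The other lists that differed from the remaining genes at the promoter were cell cycle, housekeeping, hepatocyte, and Hox with other developmental regulators. All 16 cell cycle genes and all 16 housekeeping genes were open (Fisher's exact test, p = 0.00112, adjusted p = 0.00420 for each). Cell cycle genes had a median of 4 shared peaks, at percentile 99.6 of matched lists, led by Rrm2 with 11, Mki67 with 7 and Ccnb2 with 6. The percentile was 93.9 when peaks within 1 kb of a start were left out and 95.9 with replicate 2 alone, which are not past the limit. Housekeeping genes had a median of 5.5, at percentile 100, led by Ywhaz with 22, Actb with 12 and Eef1a1 with 9. Only 1 of 12 hepatocyte genes was open, Apob (Fisher's exact test, p = 9.37e-05, adjusted p = 0.000703), while Tat, with 4 shared peaks, was not. Of the 19 Hox and other developmental regulators, 6 were open (31.6%, 95% Wilson interval 15.4 to 54.0, Fisher's exact test, p = 0.00634, adjusted p = 0.0190). Lhx2 with 10 shared peaks, Olig2 with 5 and Hoxa13 with 3 were among the open ones. This list lost its call within 2500 bp of a start (exact test, adjusted p = 0.0750) and with replicate 2 alone, where the adjusted p was the highest of its alternatives, which ranged from 0.00833 to 0.12.

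Lists of other cell types present in or near the thymus did not pass the adjusted threshold against the remaining genes. Across these and the 4 lists of more distant tissues, the adjusted p of Fisher's exact test ran from 0.0835 for muscle to 1 for endothelium. Of 16 thymic epithelium genes, 7 were open, among them Cldn4, Epcam and Aire, which drives the display of tissue antigens in the medulla. The promoter peak of Aire (ENSMUSG00000000731, chromosome 10, 78030022 to 78043610) lay in its untranslated region at 78043461 to 78043700 with 4.86 ± 1.44 (SD, n = 2). Foxn1, the master regulator of thymic epithelium (ENSMUSG00000002057, chromosome 11, 78357577 to 78386558), was not open in both replicates and had 2 shared peaks, the highest 11 kb from a start. Of 12 B lineage genes, 7 were open, including Ebf1 with 13 shared peaks, Pax5 with 9 and Blk with 6, while Igll1 and Fcrla were not. Of 14 myeloid genes, 6 were open, including Itgam, Fcgr3 and Spi1, and Csf3r was not open with 5 shared peaks. Of 11 dendritic cell and antigen presentation genes, 6 were open, including H2-Ab1, H2-Eb1 and Zbtb46, while Flt3, Ciita and Clec9a were not. Of 12 endothelial genes, 8 were open, with Pecam1 at 15 shared peaks, Egfl7 at 12 and Erg at 12, while Cdh5, Emcn and Tek were not. Of 12 fibroblast and mesenchyme genes, 5 were open, including Pdgfra, Col1a1 and Pdgfrb, and Col1a2 was not.

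Of 10 erythroid genes matched to the annotation, 3 were open, including Epor and Gata1, while Klf1 and Alas2 were not. This list did not pass the threshold (Fisher's exact test, adjusted p = 0.0876) but did with replicate 2 alone (0.0378, within a range of 0.0360 to 0.186 over its alternatives). Of 10 adipose genes, 4 were open, including Prdm16, Plin1 and Ucp1, and Adipoq was not. The highest promoter peak of Prdm16, at 154334821 to 154335020, lay at a start within the gene, which spans 154316125 to 154636873 on the minus strand. Of 12 neuron genes, 7 were open, led by Rbfox3 with 23 shared peaks, Elavl4 with 10 and Gad1 with 6, while Neurod2, Stmn2 and Neurod1 were not. The highest promoter peak of Rbfox3, at 118507981 to 118508180, also lay near a start within the gene, which spans 118489762 to 118911597 on the minus strand. An open call therefore need not concern the outermost start of a gene. Of 12 skeletal and heart muscle genes, 4 were open, including Ttn, Myl2 and Myod1, and Myh3 was not. For the 10 lists that did not pass at the promoter, the median number of shared peaks lay between percentiles 16.2 and 81.5 of matched lists. For the Hox and developmental list the percentile was 1.84, and it lay above 2.5 under all 5 alternatives, from 8.13 to 24.6.

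**Figure D3:**
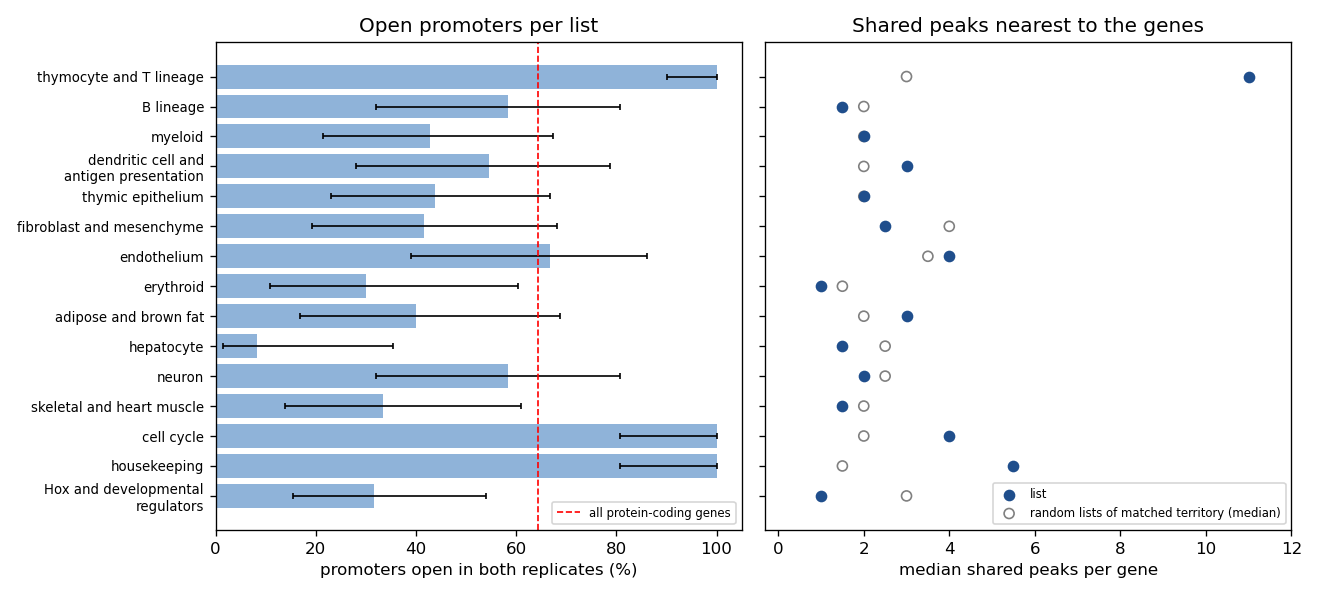
Left, share of promoters open in both replicates for each of the 15 lists, with bars starting at 0, 95% Wilson intervals, and a dashed line at the share of all protein-coding genes (64.4%). Right, median number of shared peaks per gene for each list (filled) and the median of 10000 random lists of matched territory (open), with the thymocyte and T lineage list at 11 against 3.

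Across all 21938 protein-coding genes, 16608 had at least 1 shared peak nearest to them and the median was 2. The 10 genes with the most were Gse1 with 62, Foxp1 with 54, Pde4d with 51, Bcor with 47, Ulk4 with 45, Zmiz1 with 45, Lpp with 44, Prex1 with 44, Sept9 with 41 and Trp53i11 with 41. Most of these genes have long territories, from 244 kb at Sept9 to 1565 kb at Pde4d, whereas that of Trp53i11 spans 96.5 kb. Zmiz1 encodes a cofactor of Notch1 and Bcor a transcriptional corepressor. The highest peak nearest to Prex1, at 166713801 to 166714080 on chromosome 2, lay 109 bp from a start.

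The 5 shared peaks of highest mean rank were not at T lineage genes. The first lay between genes on chromosome X at 143482981 to 143483140, 35.5 kb from the start of Pak3, with values of 89.9 in replicate 1 and 57.4 in replicate 2. The second lay in an intron on chromosome X at 169998241 to 169998420, 11.3 kb from Gm21887, with values of 45.4 and 46.2. The others were at chromosome 17, 6430021 to 6430180, 11 bp from a start of Dynlt1b; chromosome 17, 39846781 to 39846920, within 1 kb of a start in an exon that is not coding; and chromosome 13, 17694881 to 17695100, 201 bp from a start of Mplkip. The last 3 had mean values of 41.2 ± 24.1, 37.5 ± 9.58 and 33.8 ± 21.9 (SD, n = 2).

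Binding motifs of CTCF, ETS, RUNX and E proteins were more frequent at the centres of shared peaks than in the flanks. Of 25 motifs, 16 were enriched and 5 depleted in 150 bp windows at peak centres relative to flanking windows (two-sided Fisher's exact test, adjusted over the 25 motifs). With peaks and flanks matched on GC content, which keeps 59354 of the 80482 peak windows, 21 were enriched and 1 depleted. The CTCF motif was in 8.14% of peak centres and 0.0252% of flanks, a 323-fold difference that was 177-fold with replicate 2 alone and 1271-fold in windows of 50 bp. With replicate 2 alone the motif was in 4.74% of peak centres. The ETS motif was in 6.25% and 1.17%, a 5.33-fold difference. The PU.1 motif, of a myeloid and B lineage factor, has a consensus that contains the ETS one and was 7.86-fold enriched, in 55 peak windows against 10 flanking windows. With peaks and flanks matched on GC content PU.1 was 16-fold enriched, in 48 windows against 3. The E protein motif was in 14.5% and 6.69%, or 2.16-fold, and the RUNX motif in 3.28% and 1.5%, or 2.19-fold (exact test, adjusted p = 5.66e-149). The TCF/LEF motif, bound by the products of Tcf7 and Lef1, was 1.27-fold enriched (exact test, adjusted p = 9.80e-20). RUNX was enriched 2.74-fold in peaks over 1 kb from a start and did not pass the threshold in peaks within 1 kb (1.12-fold, exact test, adjusted p = 0.127). TCF/LEF was enriched 1.54-fold in the former and depleted, at 0.770-fold, in the latter. The difference between the peak classes was not tested.

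Promoter peaks were instead rich in motifs of factors that act at many promoters. SP/KLF was enriched 8.58-fold within 1 kb of a start, NFY 6.22-fold, NRF1 66.0-fold and CREB/ATF 20.2-fold, against 3.76, 1.17, 11.3 and 3.45 in the other peaks. The GATA, HNF4, POU octamer, SOX and FOX motifs were depleted among all shared peaks, at 0.677, 0.664, 0.793, 0.657 and 0.777-fold. HNF4 did not pass in windows of 50 bp (exact test, adjusted p = 0.0895), nor POU octamer in the stricter 50% of peaks (adjusted p = 0.182). Peak centres held 55.5% GC and flanks 46.1%. With peaks and flanks matched on GC content, which also leaves out GC-rich peaks and lowers the GC of those kept to 51.8%, the fold was 2.08 in place of 7.29 for SP/KLF, 12.3 in place of 38.6 for NRF1, 5.38 in place of 8.93 for CREB/ATF and 2.03 in place of 2.61 for NFY. The NRF1 fold was 22.4 with replicate 2 alone. In the matched set, RUNX stood at 3.4-fold, and IRF, MEF2 and C/EBP, which had not passed, were enriched 1.63, 2.2 and 1.42-fold. In this set, only SOX was depleted among the 25 motifs, POU octamer and FOX were enriched 1.49-fold and 1.37-fold, and GATA stood at 1.06-fold (exact test, adjusted p = 0.107).

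**Figure D4:**
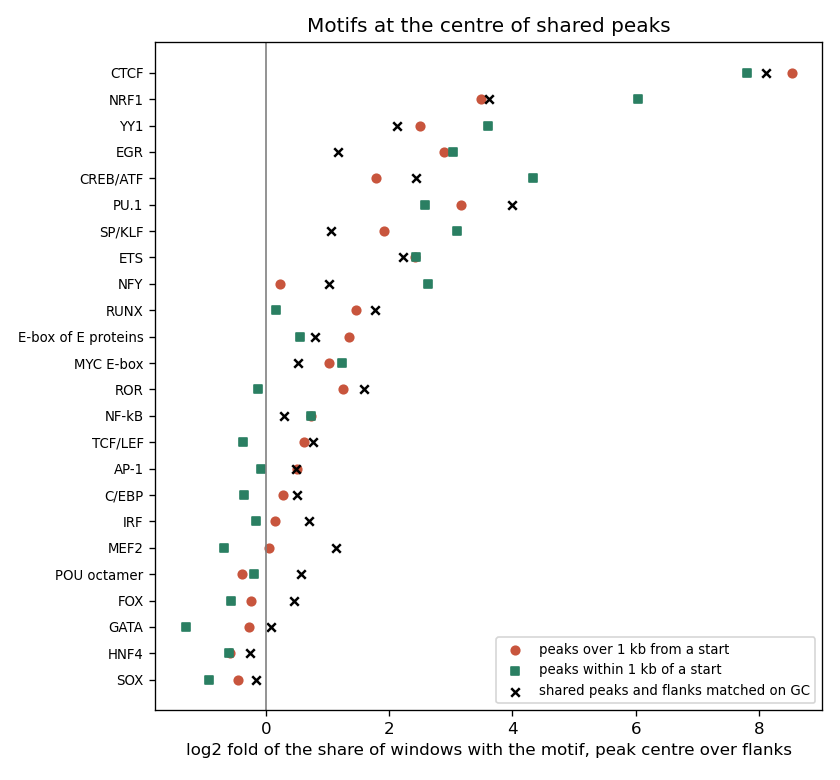
Log2 fold of the share of windows holding each motif, peak centre over flanks, for 24 of the 25 motifs (1 with too few matches is left out). Circles are peaks over 1 kb from a start, squares peaks within 1 kb and crosses the shared peaks and flanks matched on GC content, and RUNX, TCF/LEF and ROR lie further right in the circles and SP/KLF, NFY, NRF1 and CREB/ATF in the squares.

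Footprints, short stretches protected from cutting within accessible DNA, held sites of several motif families above the rest of the same peaks. Replicate 1 had 272847 footprints and replicate 2 had 358372, with a median length of 10 bp in each. At least 1 footprint was found in 83.4% of the peaks of replicate 1 (95% Wilson interval 83.2 to 83.7) and 72.3% of those of replicate 2 (95% Wilson interval 72.1 to 72.5). With the same number of top peaks from each replicate, the order turned, at 83.4% and 86.2%. Of the footprints, 59.9% of replicate 1 and 45.7% of replicate 2 overlapped a footprint of the other replicate. Of 150914 shared footprints, 100535 were tested against same-length intervals of the same peaks. Among 25 motifs, 13 were enriched and 4 depleted in them. The CTCF motif was in 3.05% and 0.00497%, a 613-fold difference that was 155-fold with replicate 2 alone. Its share of footprints was 1.33% with replicate 2 alone and 1.59% with replicate 1 alone. Other enriched motifs were SP/KLF in 2.83% and 0.187%, TCF/LEF in 0.766% and 0.270% (2.84-fold), RUNX in 0.598% and 0.278% (2.15-fold) and ETS in 1.20% and 0.665% (1.80-fold). SP/KLF was in 1.17% with replicate 2 alone and 1.57% with replicate 1 alone, and with replicate 1 alone TCF/LEF was in 0.412%, RUNX in 0.397% and ETS in 0.790%. The SP/KLF fold was 27.3 without the margin and 15.1 with it. CREB/ATF was enriched 17.4-fold (66.4 without the margin) and EGR 6.75-fold (11.5 without it). MYC E-box was enriched 2.58-fold, YY1 2.31-fold, IRF 1.59-fold and NFY 1.31-fold. Footprints and background intervals were not matched on GC content. The NRF1 motif was in 228 footprints and in none of the background intervals, at least 76-fold higher against a floor of 3 counts over the background. The E protein motif, enriched at peak centres, did not pass the threshold here (1.02-fold, exact test, adjusted p = 0.605) but did in replicate 2 alone (1.17-fold, adjusted p = 1.08e-12). FOX was depleted at 0.364-fold, POU octamer at 0.538-fold and GATA at 0.660-fold, and each stayed depleted under every alternative. AP-1 was depleted at 0.656-fold but stood at 1.06-fold in replicate 2 alone (exact test, adjusted p = 0.254). NF-kB was enriched 1.47-fold but stood at 0.953-fold without the margin of 5 bp (exact test, adjusted p = 0.933) and did not pass in replicate 1 alone (1.25-fold, adjusted p = 0.0851).

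The sex chromosomes, of which males carry 1 X and 1 Y, held fewer shared peaks than the autosomes. Autosomes had 32.7 shared peaks per Mb, chromosome X 13 and chromosome Y 0.613, ratios of 0.397 and 0.0187. These densities are over all known bases, 88.1 Mb on chromosome Y. How many of those bases reads could be placed on was not measured, so a low density need not mean low accessibility. Chromosome X held 5.80 protein-coding genes per Mb, near chromosome 12 with 5.50, which had 28.5 shared peaks per Mb. Among autosomes the density ran from 24.3 on chromosome 3 to 53.7 on chromosome 11. The median peak value on chromosome X was 0.592 of the autosomal median in replicate 1 and 0.612 in replicate 2. Among the stricter 50% of peaks the ratio was 0.264 for X and 0.00840 for Y, and with replicate 1 alone the ratio for Y was 0.0345.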

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

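The comparison of cut rates outside peaks and the tests of the number of peaks were chosen after the results were seen. The cut rate lists were used above only to describe the peak lists, and part of their bases lay outside the peaks. Bases directly beside a peak count as outside, and the distance to the nearest peak was not measured. At an FDR of at most 0.001, 8.03 Mb in replicate 1 and 18.1 Mb in replicate 2 lay outside the peaks of the same replicate, or 38.5% and 44.6% of all bases at that limit. There are no control samples to set a level for such bases, so these values are a description and not a test.

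Replicate 2 had 1.69 times as many peaks as replicate 1, and the peaks of replicate 2 alone were more numerous near T lineage genes than near genes matched on territory length. A looser FDR limit was argued against, since among peaks with an FDR of at most 0.001 the ratio of peak numbers was 1.69 as well. The larger lists of both replicates reach the same FDR limit of 0.05, so this ratio had little room to move. An equal FDR in separate libraries need not mean an equal cut on the signal. The lowest peak value was 0.0356 in replicate 1 and 0.0102 in replicate 2, so a looser cut on the signal was not tested. Deeper sequencing and a higher signal over background in replicate 2 cannot be told apart, because the scale of the peak value is not given. If a step of the value is worth 1 tag, replicate 2 had 0.873 of the depth of replicate 1, and the median log2 ratio of the value at shared peaks, 0.86, would then be a candidate explanation by signal. A difference between the animals remains open, and no biological explanation was tested.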

How the results depend on the processing

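All alternatives were planned. The T lineage, housekeeping, cell cycle and hepatocyte lists kept their promoter call under all 7 alternatives, and the T lineage and housekeeping lists their percentile call under all 5. Elsewhere the cause was not tested. By Fisher's exact test, promoter calls were gained within 250 bp by the myeloid (adjusted p = 0.0400), thymic epithelium (0.0360), erythroid (0.0360) and muscle lists (0.00116); in the stricter 50% by the adipose list (0.0172); with the same number of top peaks by the fibroblast and muscle lists (0.0352 each); and with the smaller peak list by the myeloid (0.0491), fibroblast and muscle lists (0.0389 each). The Hox list lost its call within 2500 bp (0.0750) and ranged from 0.00907 to 0.12 with a replicate left out, the erythroid list from 0.0378 to 0.0826. Percentiles of the Hox list were 21.4 within 20 kb, 19.4 without peaks near a start, 24.6 in the stricter 50% and 8.13 to 11.2 with a replicate left out. Those of the cell cycle list were 93.9 without peaks near a start and 95.9 to 98.4 with a replicate left out. The fibroblast list was called in the stricter 50% at 1.62. Shares of shared peaks in replicates 1 and 2 were 73.8% and 43.8% with reciprocal overlap, 97.9% and 58.4% in the stricter 50%, 78.0% and 77.8% with the same number and 93.0% and 54.5% in the smaller lists, where the Jaccard index was 0.479, 0.529 and 0.452 in the last 3. Correlations were 0.951 on log2 values, 0.948 (Pearson) and 0.941 (Spearman) with the same number, and 0.948 and 0.951 with reciprocal overlap. The promoter share was 22.3% within 250 bp, 46.8% within 2500 bp, 44.3% in the stricter 50% and 29.0 to 36.6% with a replicate left out. Matching peaks and flanks on GC, which keeps 59354 of 80482 peak windows, gave 1 depleted motif in place of 5 and turned GATA to 1.06-fold, POU octamer to 1.49 and FOX to 1.37. In footprints NF-kB turned to 0.953 without a margin, and AP-1 ranged from 0.654 to 1.06 with a replicate left out. Replicate 2 peaks with a footprint rose to 86.2% with the same number of peaks, and reciprocal overlap lowered shared footprints to 43.5% and 33.1%. The X and Y ratios were 0.264 and 0.00840 in the stricter 50%, and ranged from 0.382 to 0.433 and from 0.0209 to 0.0345 with a replicate left out. Of the counts of shared peaks per gene picked by the naming rule, 161 of 460 moved by over 1.5 times. The number of all peaks also changed, from 80482 to 46136 in the stricter 50% and to 161763 with replicate 2 alone, so such moves are not particular to these genes. Over their 7 alternatives the adjusted p ranged from 0.0400 to 0.548 (myeloid), 0.0360 to 0.335 (thymic epithelium), 0.0360 to 0.186 (erythroid), 0.00116 to 0.367 (muscle), 0.0172 to 0.762 (adipose), 0.0352 to 0.665 (fibroblast) and 0.00833 to 0.12 (Hox). The stricter 50% of footprints could not be taken, since their value is constant. The depth of the libraries is unknown, so what it limits was not measured.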

Other observations

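The antigen receptor loci, the choice of blocks and the lists of peaks of 1 replicate were examined only after the other results were seen, whereas the tests of repeated sequence, promoters and footprints were set before their results were seen. The rule that overlapping intervals leave a test undecided was set after these tests were run, and it moved the footprint test from excluding its explanation to undecided. It also left undecided the test of repeated sequence in the blocks, where the interval lay above the share of the other peaks. The promoter test was also judged undecided only after its result was seen. The genes named here outside the T lineage list were chosen after their values were seen.

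The density of shared peaks differed among the T cell receptor loci and among the immunoglobulin loci. The Tcra and Tcrd locus on chromosome 14 (52427928 to 54224206) held 135 shared peaks, or 75.2 per Mb, and the Tcrb locus on chromosome 6 (40891229 to 41558452) held 50, or 74.9 per Mb. The Tcrg locus on chromosome 13 held 6, or 34.3 per Mb. The Igh locus, the immunoglobulin heavy chain genes on chromosome 12 (113254830 to 116010093), held 148, or 53.7 per Mb, whereas the Igk light chain locus on chromosome 6 held 6, or 1.89 per Mb, and the Igl locus 2, or 10.0 per Mb. The autosomes as a whole had 32.7 per Mb. These counts depend on the library: replicates 1 and 2 alone had 22 and 27 peaks at Igk, 153 and 238 at Tcra and Tcrd, 53 and 95 at Tcrb, 6 and 14 at Tcrg, 169 and 247 at Igh, and 2 each at Igl. The highest peak of the Tcrb locus, at 41118281 to 41118460, had a value of 7.20 ± 2.62 (SD, n = 2), and that of the Igh locus, at 114587341 to 114587520, had 9.11 ± 3.91.

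Peaks of the smaller list of replicate 2 that overlapped no peak of replicate 1 numbered 33413. T lineage genes had a median of 7 of them, against 1 for matched lists, at percentile 100, and B lineage genes had 1.5 at percentile 98.7. The matching was on territory length and not on the number of shared peaks. T lineage genes also had more shared peaks, with a median of 11 against 3. The genes with the most peaks of replicate 2 alone were Nck2 with 55, Cd2 with 44, Ets1 with 44, Gse1 with 37, Fyb with 36, Sema4d with 35, Adgrg1 with 34, Trpm1 with 32 and Notch1 with 30. The same kind of peak in replicate 1 numbered 3887, with a median of 0 in each of the 15 lists.

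Of those 3887 peaks of replicate 1, 703 lay in 42 dense blocks of at least 10 peaks with gaps of at most 5 kb. Their median value was 0.125, against 0.463 for the others, whereas replicate 2 had 150 such blocks with 2242 peaks and a median value of 0.484, against 0.438. The largest blocks of replicate 2, with 34, 32, 31, 29 and 28 peaks, lay nearest to Galk1, Dlx1, Fyb, Notch1 and Sema4d. Of these genes, Fyb, Notch1 and Sema4d are among those with the most peaks of replicate 2 alone. Block peaks also enter the counts per gene, so this match is not separate evidence. In replicate 1, one block with 29 peaks lay at 110027275 to 110048251 on chromosome 4, one with 27 peaks at 169969853 to 169992480 on chromosome X near Mid1, and one with 26 at 28084681 to 28103200 on chromosome 7 near Fcgbp. Sequence repeated within the reference is a candidate explanation. Of the block peaks of replicate 1, 6.83% (95% Wilson interval 5.19 to 8.94) had their central 31 bases at 2 or more places, against 4.46% of the others (3.80 to 5.23). The interval of the block peaks lay above the share of the others, as predicted beforehand. It overlapped the interval of the others, and such overlap is not a test of the difference, so the explanation was not decided. Raised regional background was not decided either, since 41.8% of block peaks (38.2 to 45.5) held a footprint, against 38.7% of the others (37.0 to 40.4). Differences in copy number and the mapping of reads from the CAST/EiJ chromosomes to the reference were not tested and remain open. Both animals are labelled as the same cross, so such mapping by itself would not set replicate 1 apart.

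The 5 highest shared peaks raised the hypothesis that several copies of a sequence pile on 1 place, since 2 of the 5 had their central 31 bases at 2 places of the reference. Of the 200 highest shared peaks, 2.5% (95% Wilson interval 1.07 to 5.72) had their central 31 bases at 2 or more places of the reference, against 2.10% of the others, so the test did not decide. Promoters open in most cells were not decided either: 92.5% of the 200 lay within 1 kb of a start, against 36.2% of the others, but peaks near a start had higher medians in both replicates and openness in other cells was not measured. Copies missing from the reference were not tested.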
